A study of Drosophila melanogaster with 9 samples.

How the data were processed

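RNA sequencing was performed on midguts dissected from adult virgin Drosophila melanogaster females of 3 groups with 3 libraries each: control females, females mutant for transformer (tra), and tra mutant females in which the female form of tra was returned to adult intestinal stem cells (called the rescue here). Per the labels, the flies were of a w1118 background, each replicate was a pool of 30 midguts, and poly(A) libraries were made with a stranded mRNA kit from 500 ng of RNA and read from both ends over 100 bases. The labels give the age as 15 days, and their treatment text gives 3 days at 18 °C and then 10 days at 29 °C to switch on the transgene. They name 2 models of one sequencer, so the model is not stated here. Group and replicate number were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical in part.

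The values used were the counts the authors deposited, whole numbers of reads or read pairs per gene for each library, not normalized. The submitters' processing notes name TopHat2 2.0.11, HTSeq and the genome build dm3. The HTSeq version, its strand setting and its overlap mode were not given in the sources used here, so genes that overlap another gene are treated as uncertain. Of 138 named genes with a location, 39 overlapped a gene on the other strand and 15 one on the same strand. Each count table held 15682 gene identifiers, of which 15002 were paired with a symbol through the reference name table and 680 were not; the latter took 4.84% to 5.60% of a library's gene counts. The chromosome of a gene and its neighbours came from the Ensembl release 115 annotation of BDGP6, a different build from that of the counts, so no coordinates are given. Mitochondrially encoded genes (37 identifiers) were listed at 0 in all 9 libraries.

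Gene counts per library were 93765308, 105248239 and 104328153 in control, 101017780, 98721986 and 99445431 in the mutant, and 108455374, 84839470 and 88431469 in the rescue. Levels are given in CPM, counts per 1000000 gene counts of the library after TMM scaling. At this depth, a count of 0 in the shallowest library, rescue replicate 2, allows up to 3 counts, or 0.0354 per 1000000 gene counts before TMM scaling. Counting intervals are 95% intervals and cover counting error only, because PCR copies were not marked. The 5 lines of each table that name no gene were left out of library sizes and tests. Alignments at more than 1 place took 14.6% to 22.9% of all counted alignments, alignments outside genes 1.30% to 1.83%, and alignments matching more than 1 gene 0.822% to 1.09%. The lines for low quality and for unaligned reads were at 0. Replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom of 128.4 to 1055 for each pair, so no library was a copy of another of its group.

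Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr at its settings of 10 counts per gene and 15 in total, which left 10088 genes, and library sizes were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to all 9 libraries, so that the groups shared 1 estimate of the spread. Adjusted p in the text, unless another tool is named, is the Benjamini-Hochberg value of edgeR's quasi-likelihood test over the 10088 genes, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the test's F statistic. The common biological coefficient of variation was 0.246. Alternatives chosen before the data were examined were RLE size factors, upper-quartile scaling, library totals alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, the replicate number as a block, fits on the 6 libraries compared, and leaving out each library in turn. Single values such as shares of alignments were compared by two-sided exact permutation tests in scipy 1.17.1 under Python 3.11.15, for which 3 against 3 libraries cannot give a p under 0.1.

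The replicate numbers in the sample titles were checked for pairing. Deviations from the group means, correlated across genes, gave r = 0.204, 0.176 and 0.17 for control and mutant libraries of the same number. Libraries of unlike number, over all groups, reached 0.167. The numbers were read as possible pairs of control and mutant libraries, with the replicate block as an alternative fit. The main fit had no block, so its counts and adjusted p take no account of such pairs.

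Lists of genes were fixed before the data were examined: 28 lists for sex determination, classical sex-biased transcripts, dosage compensation, candidate effectors of tra named by the study, progenitors, the cell cycle, trypsin and chymotrypsin-like proteases, carbohydrate digestion, lipid handling, enteroendocrine cells, enterocyte and regional identity, visceral muscle, neurons, trachea and haemocytes, fat body, ovary, testis, accessory gland, Malpighian tubule and hindgut, antimicrobial and gut immune effectors, JAK-STAT, EGFR and JNK signalling, insulin signalling, heat shock, detoxification, Y-linked genes, transgene-associated genes, cytoplasmic ribosomal proteins and mitochondrially encoded genes. Of their members, 29 were not analysed here. As sets, 24 lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, with fry and with the block. Counts of list members that passed are given over all genes tested and adjusted over the list alone.

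Genes were named by a rule fixed before the data were examined. It took tra and the members of the sex determination, candidate effector and transgene-associated lists. It added the 8 largest changes each way in mutant against control and in rescue against mutant and the 5 largest each way in rescue against control, among genes that passed, averaged at least 1 CPM and did not overlap between the groups. It also took up to 12 genes that changed in the mutant and changed back in the rescue, and up to 4 passing members (or 2 members where none passed) of each list. This gave 140 genes. Other genes are named only as members of a list or where the text says that they were chosen after their values were seen.

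The procedure was tested on simulated counts with the real means and library sizes and 200 changed genes among 10088, 50 per fold size. The changed genes were drawn from those averaging at least 1 CPM, so the recovery below does not cover genes at lower levels. In mutant against control it recovered 8%, 68%, 90% and 100% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, with 4 false calls. In rescue against mutant it recovered 10%, 54%, 98% and 100%, with 0 false calls, and in rescue against control 10%, 62%, 94% and 100%, with 7 false calls. Unchanged groups that share the mutant or the control libraries were simulated in 20 draws. Tables were handled with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.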

Results

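Gene expression was measured by RNA sequencing of midguts from adult virgin females in 9 libraries, 3 from control females, 3 from females mutant for transformer (tra), and 3 from tra mutant females carrying the female form of tra in adult intestinal stem cells (the rescue). tra encodes a splicing regulator that directs female sexual differentiation in somatic cells. Gene counts per library ranged from 84839470 to 108455374, and 10088 genes had enough counts to be tested. The first principal component (38.6% of the variance) separated the control libraries, at -34.6, -34.5 and -64.2, from the mutant libraries at 18.8 to 27.0 and the rescue libraries at 19.0 to 25.6. Control replicate 3 stood apart from the other control libraries on this component, and correlations between control libraries were 0.973 to 0.983, below the 0.987 to 0.989 of the mutant and the 0.983 to 0.985 of the rescue. Levels below are CPM as mean ± SD over n = 3 libraries, and log2 fold changes are given with their SE.

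tra itself (FBgn0003741, chromosome arm 3L) was read first, as a check of the labels. Its counts were 821, 650 and 742 in control, 1, 2 and 1 in the mutant, and 756, 472 and 294 in the rescue. The levels were 7.36 ± 1.04, 0.0136 ± 0.00643 and 5.18 ± 1.60 CPM. Relative to control, tra fell in the mutant by a ratio of summed counts of 546 (95% counting interval 213 to 2004), with a log2 fold change of -8.97 ± 0.41 (edgeR adjusted p = 1.1e-05). It rose from mutant to rescue by 8.46 ± 0.41 (edgeR adjusted p = 2.34e-05), and the rescue did not differ from control past the threshold (-0.50 ± 0.24, edgeR adjusted p = 0.215). The counts alone do not separate the transgene from the endogenous gene, and tra overlaps a gene on the other strand. The 1, 2 and 1 counts of the mutant argue against the endogenous gene as the source of the rescue counts, if the rescue carried the same mutant alleles. The other 10 tested members of the sex determination list did not pass in mutant against control. dsx, the transcription factor gene spliced under tra control, measured 25.4 ± 4.49, 35.5 ± 6.08 and 46.5 ± 5.62 CPM in control, mutant and rescue (mutant against control 0.48, edgeR adjusted p = 0.118; rescue against control 0.87 ± 0.17, edgeR adjusted p = 0.0142). The list as a set did not pass (camera adjusted p = 0.949).

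**Figure D1:**
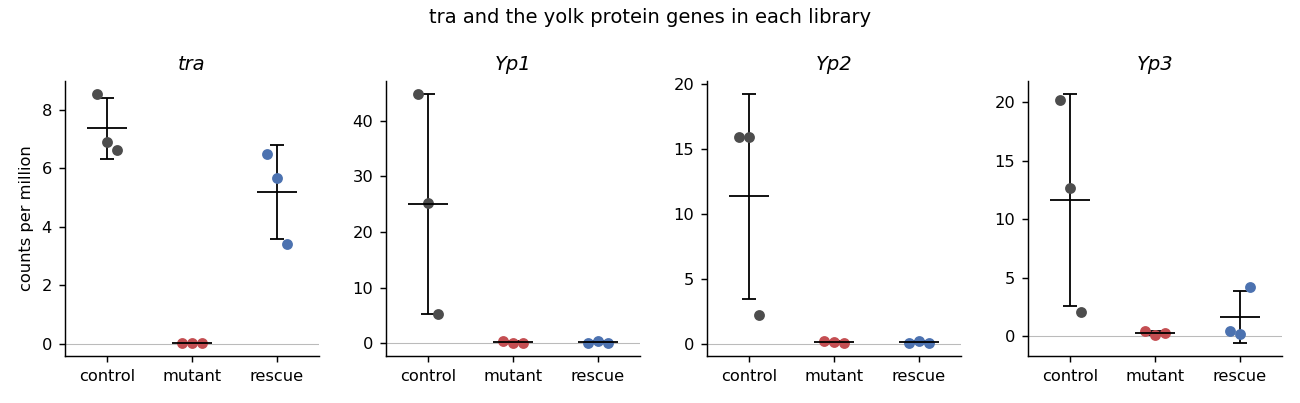
Levels of tra and of the yolk protein genes Yp1, Yp2 and Yp3 in CPM (vertical axis, linear) in each of the 9 libraries by group (horizontal axis), with points for libraries, horizontal bars for means and whiskers for SD. tra lay at 6.62 to 8.55 CPM in control and at 3.40 to 6.49 CPM in the rescue, and Yp1 lay at 5.23 to 44.9 CPM in control and at or below 0.367 CPM in the other 6 libraries.

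The comparison of mutant with control asked what loss of tra changed in the female midgut. Yolk protein genes, the protease gene Jon99Fi and the strongly expressed genes SMC2 and CG31041 fell, while the amylase gene Amy-d, several maltase genes, the lysozyme genes LysB to LysE and several detoxification enzymes rose. In total 369 genes rose and 304 fell, of which 234 and 195 by at least 2-fold. Among the largest increases were CG34215 (FBgn0085244, arm 2R), from 0.0388 to 29.8 ± 7.93 CPM (log2 fold change 9.62 ± 0.75, edgeR adjusted p = 0.000157), and elfless (FBgn0032660, 2L), from 0.00709 to 4.98 ± 1.43 CPM (9.29 ± 0.76). These genes had 11 and 2 counts over the control group, and the ratios of summed counts were 824 (interval 461 to 1652) and 751 (interval 208 to 6205). Klp54D, a kinesin-family motor protein gene, rose from 0.0373 to 6.29 ± 0.69 CPM (7.29 ± 0.65), and Arr1, an arrestin of photoreceptor cells, from 0.177 to 14.0 ± 5.46 CPM (6.33 ± 0.62). CG31089 rose from 2.48 ± 1.09 to 75.1 ± 8.79 CPM, and CG11893 from 4.96 ± 4.60 to 132 ± 29.6 CPM. SMC2, which encodes a condensin subunit, fell from 206 ± 61.5 to 5.01 ± 1.19 CPM (-5.36 ± 0.35, edgeR adjusted p = 5.27e-05), and CG31041 from 234 ± 99.7 to 7.50 ± 2.16 CPM (-4.96 ± 0.48, edgeR adjusted p = 0.000479). Sdic3, a member of a tandem family of near-identical copies whose reads cannot be assigned with certainty, fell from 4.99 ± 1.02 to 0.0472 CPM.

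The yolk protein genes, which are transcribed in the female fat body and in ovarian follicle cells, stood out among the classical sex-biased transcripts. Of the 6 tested members of that list, 3 fell and 3 did not pass (4 fell when adjusted over the list alone). Yp1 (FBgn0004045, X) fell from 25.1 ± 19.8 to 0.179 ± 0.163 CPM (-7.13 ± 1.09, edgeR adjusted p = 0.00538), Yp2 from 11.4 ± 7.91 to 0.170 ± 0.0829 CPM (-6.06 ± 0.80, edgeR adjusted p = 0.00257), and Yp3 from 11.7 ± 9.10 to 0.261 ± 0.143 CPM (-5.47 ± 1.25, edgeR adjusted p = 0.0311). The Yp3 call was lost without control replicate 1, control replicate 2 or any 1 of the 3 mutant libraries, with edgeR adjusted p up to 0.112. The list passed as a set (camera adjusted p = 0.0235), with adjusted p = 0.711 with an estimated correlation. Yp1 differed between the control libraries (4309, 2369 and 586 counts), and so did apolpp, a fat body lipoprotein gene (1393, 804 and 326 counts). Of the 13 tested fat body markers, which include the yolk proteins, 1 rose and 4 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.114), and without control replicate 3 the counts were 0 and 7. Among them Lsp1gamma fell by 3.21 ± 0.55 on the log2 scale (edgeR adjusted p = 0.00875). None of the 6 tested ovary markers passed with edgeR, with 0 at an unadjusted p under 0.05 and 0 with DESeq2.

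Many genes of carbohydrate digestion rose. Of 21 tested members, 9 rose, 0 fell and 12 did not pass (16 rose and 1 fell adjusted over the list alone). Amy-d, an alpha-amylase gene (FBgn0000078, 2R), rose from 1424 ± 345 to 7412 ± 630 CPM (2.38 ± 0.23, edgeR adjusted p = 0.000495), while its near-identical neighbour Amy-p measured 0.66 on the log2 scale (edgeR adjusted p = 0.144), and reads of this pair are uncertain. The maltase genes Mal-A2 (972 ± 83.5 to 1913 ± 204 CPM, 0.98 ± 0.16, edgeR adjusted p = 0.00796) and Mal-B2 (5.05 ± 2.31 to 17.5 ± 3.56 CPM, 1.79 ± 0.33, edgeR adjusted p = 0.0117) also rose. Mal-A4 rose by 1.81 ± 0.34 (edgeR adjusted p = 0.0138; 0.0522 without mutant replicate 2). The maltase gene Mal-B1 went the other way without passing (-4.88, edgeR adjusted p = 0.149), and passed as lower with DESeq2 (0.0381). The set passed with camera adjusted p = 5.38e-10, and with adjusted p = 0.219 with an estimated correlation. With every scaling tried in edgeR, 9 to 12 members rose and 0 fell, and with DESeq2 15 rose and 1 fell.

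**Figure D2:**
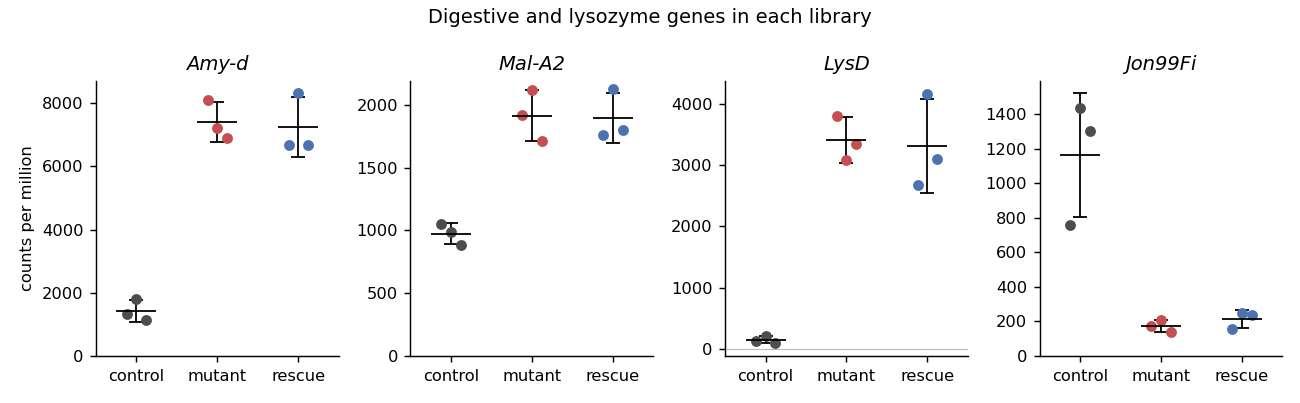
Levels of Amy-d, Mal-A2, LysD and Jon99Fi in CPM (vertical axis, linear) in each library by group (horizontal axis), with points for libraries, horizontal bars for means and whiskers for SD. Amy-d, Mal-A2 and LysD were higher, and Jon99Fi lower, in the mutant and in the rescue than in control, with group means of 1424, 7412 and 7239 CPM for Amy-d and of 1165, 173 and 213 CPM for Jon99Fi.

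Proteases and lipid genes changed in both directions. Among 30 tested trypsin and chymotrypsin-like proteases 1 rose and 2 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.146), and without control replicate 3 the number that fell was 5. With RLE factors 1 rose and 1 fell. Without rescue replicate 2, which enters here only through the shared spread, 0 rose and 1 fell. Jon99Fi, a Jonah-family protease with the near-identical neighbour Jon99Fii, fell from 1165 ± 359 to 173 ± 36.0 CPM (-2.75 ± 0.29, edgeR adjusted p = 0.000808). Among 27 lipid genes 3 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.767). The lipase gene Lip3 rose from 4.14 ± 2.55 to 62.7 ± 20.9 CPM (3.92 ± 0.44, edgeR adjusted p = 0.00105), and SCAP, a sterol-sensing chaperone, from 32.3 ± 2.38 to 48.3 ± 3.57 CPM (0.58 ± 0.10, edgeR adjusted p = 0.00931). Npc2e, of a family of sterol-binding proteins, fell from 486 ± 152 to 86.1 ± 23.5 CPM (-2.50 ± 0.40, edgeR adjusted p = 0.00677).

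A group of 4 lysozyme genes rose while most other immune effectors did not pass. Of 32 antimicrobial and gut immune effectors, 4 rose and 1 fell (4 and 4 adjusted over the list alone; 4 and 2 without control replicate 3), and the set did not pass (camera adjusted p = 0.681). The 4 were LysB, LysC, LysD and LysE, neighbouring digestive lysozyme genes of similar sequence between which reads are uncertain, while LysP, LysS and LysX did not pass (edgeR adjusted p = 0.0548, 0.0637 and 0.247). LysD rose from 150 ± 56.9 to 3406 ± 367 CPM (4.50 ± 0.32, edgeR adjusted p = 7.64e-05) and LysC from 35.1 ± 13.1 to 935 ± 102 CPM (4.73 ± 0.39, edgeR adjusted p = 0.000195). The member that fell was CecC, a cecropin gene near the limit of detection (0.124 ± 0.0919 CPM in control and 0.0035 CPM in the mutant, edgeR adjusted p = 0.0307). Of 51 detoxification genes, 10 rose and 1 fell (16 and 4 adjusted over the list alone; 12 and 2 without control replicate 3). Cytochrome P450 gene Cyp28a5 rose from 34.0 ± 6.68 to 117 ± 21.5 CPM (1.78 ± 0.19, edgeR adjusted p = 0.000808), the glutathione transferase gene GstE8 from 76.1 ± 24.4 to 208 ± 23.8 CPM (1.45 ± 0.23, edgeR adjusted p = 0.00661), and Cyp6g2 fell from 6.25 ± 1.03 to 1.96 ± 0.482 CPM (-1.67 ± 0.22, edgeR adjusted p = 0.00257). The detoxification set passed with camera adjusted p = 0.000123, and with adjusted p = 0.219 with an estimated correlation.

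Among genes of enteroendocrine cells a peptide hormone gene and a secretory gene rose. Of 24 tested markers 2 rose and 1 fell (7 and 2 adjusted over the list alone). Tk, which encodes tachykinin peptides, rose from 99.0 ± 15.3 to 175 ± 9.04 CPM (0.82 ± 0.14, edgeR adjusted p = 0.00748) and Cadps, which acts in dense-core vesicle release, from 3.80 ± 0.488 to 9.41 ± 0.997 CPM (1.31 ± 0.16, edgeR adjusted p = 0.00201). The peptide gene Orcokinin fell by 0.61 ± 0.15 (edgeR adjusted p = 0.0362), a call that was lost with the replicate block, with the 6 libraries alone, and without control replicate 1 or 2 or any 1 mutant library (edgeR adjusted p up to 0.113). The set passed with camera adjusted p = 0.0188, and with adjusted p = 0.711 with an estimated correlation. Of 11 neuronal markers 1 rose (1 adjusted over the list alone; camera adjusted p = 0.0363 and adjusted p = 0.607 with an estimated correlation). It was brp, of the presynaptic active zone (3.31 ± 0.377 to 5.54 ± 0.19 CPM, 0.75 ± 0.14, edgeR adjusted p = 0.0148), whose call was lost with the 6 libraries alone and without mutant replicate 1 or 2 (edgeR adjusted p up to 0.0574).

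Cell cycle and ribosomal protein genes were lower as sets, with few single calls. Of 49 cell cycle genes 1 fell, SMC2 (1 adjusted over the list alone), with a list median of -0.93 (camera adjusted p = 0.00131 and adjusted p = 0.785 with an estimated correlation). Control replicate 3 held the highest levels of CycB and Mcm7, which did not pass with edgeR, and without it their log2 fold changes moved from -1.52 to -0.16 and from -1.56 to -0.44. Of 79 ribosomal protein genes 2 fell (0 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 5.38e-10 and adjusted p = 0.772 with an estimated correlation). Without control replicate 3, 7 ribosomal protein genes fell, and with the replicate block 0 did. None of the 19 progenitor markers passed with edgeR, with 1 higher and 4 lower at an unadjusted p under 0.05 and 0 higher and 1 lower with DESeq2 (camera adjusted p = 0.799). For the 17 visceral muscle markers none passed with edgeR (1 higher and 9 lower at an unadjusted p under 0.05, 1 and 4 with DESeq2), and the set was lower with camera adjusted p = 0.00499 and adjusted p = 0.772 with an estimated correlation. Of 9 tracheal and haemocyte markers 1 rose and 1 fell (1 and 5 adjusted over the list alone, 1 and 3 with the replicate block), and the set passed only with the block (camera adjusted p = 0.0142 against 0.0551, and adjusted p = 0.771 with an estimated correlation). Among the Malpighian tubule and hindgut markers 1 of 15 rose (1 adjusted over the list alone, camera adjusted p = 0.146). None of them rose without control replicate 3, without rescue replicate 2 or with the block. Among the insulin signalling genes 1 of 15 fell (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.959). None of these fell with library totals or without rescue replicate 2.

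No member passed with edgeR in 8 lists of 113 genes (4 higher and 21 lower at an unadjusted p under 0.05, 2 and 8 with DESeq2). Besides the progenitor, muscle and ovary markers these were dosage compensation (camera adjusted p = 0.522), enterocyte and regional identity (0.938; 1 gene fell without control replicate 3), accessory gland (0.938), JAK-STAT, EGFR and JNK signalling (0.101; 1 gene fell with the replicate block) and heat shock genes (0.959). The list median and the direction of the set test differed in sign for accessory gland (median 0.11) and heat shock genes (median -0.44), and the mean and the test did for sex determination (mean -0.71). The transgene-associated list held 2 tested genes, tra and w, and passed through tra (camera adjusted p = 0.0157 and adjusted p = 0.219 with an estimated correlation), while the eye colour gene w measured -0.20 (edgeR adjusted p = 0.587). All 6 Y-linked genes analysed here were at 0 in the 9 libraries, as were the 37 mitochondrially encoded genes. Such zeros do not tell genes that were not transcribed from genes that were not counted. Of 20 testis markers 18 had under 10 counts in every library, and mia, the 1 marker tested, did not pass.

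Of the candidate effectors of tra named by the study, 2 were analysed here, and since the study chose them on these samples their count is not independent evidence. Spn88Eb, a serpin gene, had 65, 7 and 64 counts over the control, mutant and rescue libraries. It fell in the mutant (-3.14 ± 0.75, edgeR adjusted p = 0.0372) and the difference from mutant to rescue did not pass with edgeR (3.21, adjusted p = 0.214) and passed with DESeq2 (adjusted p = 0.0234; 0.0234 to 0.768 over the alternatives). The Spn88Eb call was lost without control replicate 2 or any 1 of the mutant libraries (edgeR adjusted p up to 0.132). Him had 2 counts in each group and was not tested.

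The counts of 369 and 304 genes moved with single mutant libraries. Without mutant replicate 1, 2 or 3, 201, 200 and 236 genes rose and 128, 136 and 114 fell. With the replicate block and only the 6 libraries of the comparison, 227 rose and 152 fell.

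The comparison of rescue with mutant asked what returning tra to the stem cells changed. Besides tra, 18 genes rose and 28 fell, of which few were members of the lists. Among the increases was DptA, which encodes the antibacterial peptide diptericin A, from 0.185 ± 0.158 to 34.3 ± 27.9 CPM (7.54 ± 0.89, edgeR adjusted p = 0.00487; 0.0613 without mutant replicate 1), with 65.0, 10.4 and 27.5 CPM in the 3 rescue libraries. CG30026 (FBgn0050026, 2R) rose from 2.40 ± 0.444 to 43.8 ± 14.3 CPM (4.19 ± 0.30, edgeR adjusted p = 0.000427), rau from 2.32 ± 0.385 to 10.4 ± 1.27 CPM (2.17 ± 0.20, edgeR adjusted p = 0.0012), and CG12934 from 1.85 ± 0.343 to 6.87 ± 1.15 CPM (1.89 ± 0.22, edgeR adjusted p = 0.00417). CG12133 had 4 counts in the mutant and 1008 in the rescue, a ratio of 268 (interval 104 to 984; edgeR adjusted p = 0.0128, up to 0.107 without any 1 mutant library or without rescue replicate 1). CG34054 fell from 3.63 ± 0.522 to 0.405 ± 0.142 CPM (-3.15 ± 0.31, edgeR adjusted p = 0.00161). Of the 47 genes, 31 also differed between rescue and control in the same direction, 27 of them without a call in mutant against control.

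There were 15 genes that changed in the mutant and changed back in the rescue, 13 up and then down and 2 down and then up. Those with a symbol were tra, CG17470, CG34215, elfless, Klp54D, rdo, CG42692, Cyp12d1-p, lectin-28C, CG5348, CG4734, Cyp6a13 and Cyp9b2, and 2 had no symbol in the table used here. The calls of CG42692, CG5348, CG4734 and Cyp9b2 between rescue and mutant were lost without any 1 mutant or rescue library and with the replicate block. Those of CG4734 and Cyp9b2 were also lost with the filter of 1 CPM in 3 libraries, and that of Cyp9b2 with RLE factors, library totals and no filter. With the block the set held 14 genes, of which 10 were among the 15. Klp54D returned from 6.29 to 0.0194 CPM (-8.36 ± 0.72, edgeR adjusted p = 0.00114), elfless from 4.98 to 0.0279 CPM (-7.29 ± 0.65, edgeR adjusted p = 0.00114) and CG34215 from 29.8 to 0.251 CPM (-6.82 ± 0.61, edgeR adjusted p = 0.00114). CG17470 fell from 2.75 ± 0.781 to 0.640 ± 0.079 CPM and returned to 4.62 ± 0.633 CPM (2.85 ± 0.26, edgeR adjusted p = 0.0012). The C-type lectin gene lectin-28C rose from 7.07 ± 2.14 to 52.4 ± 5.73 and returned to 10.6 ± 3.90 CPM (-2.30 ± 0.29, edgeR adjusted p = 0.00806; 0.0604 without rescue replicate 3). Cyp12d1-p, a P450 gene with a near-identical copy, rose from 2.98 ± 2.07 to 47.5 ± 3.89 and returned to 3.58 ± 1.58 CPM (-3.72 ± 0.52, edgeR adjusted p = 0.0141; up to 0.0979 without any 1 mutant library or without rescue replicate 2 or 3). Both comparisons share the mutant libraries. Independent lists would give 1.6 such genes. Simulated unchanged groups gave at most 1, but unchanged groups give few calls, so a low count was likely beforehand. Part of the excess may come from the shared libraries, and neither number shows how large that part is. Across genes, which are not independent replicates, the fold changes correlated at -0.454 (simulated -0.495), and their covariance was -0.241 against -0.064 in simulation. The signs were opposite for 54% of genes, against 66.6% in simulation. By the correlation and the signs, changing back across all genes was no more marked than the shared mutant libraries alone would give. The count was 8 without mutant replicate 1, 9 without mutant replicate 3, 9 without rescue replicate 2, 8 without rescue replicate 3 and 24 without control replicate 3.

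**Figure D3:**
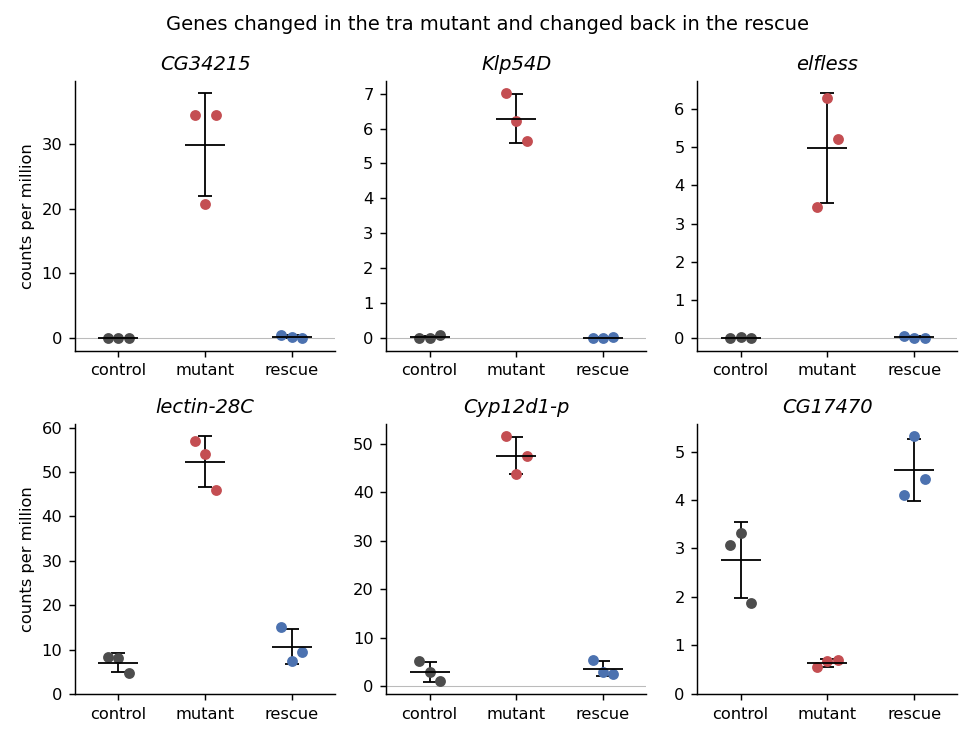
Levels of 6 genes that changed in the mutant and changed back in the rescue, in CPM (vertical axes, linear), in each library by group (horizontal axis), with points for libraries, horizontal bars for means and whiskers for SD. CG34215, Klp54D, elfless, lectin-28C and Cyp12d1-p were high only in the 3 mutant libraries, and CG17470 was low only there (0.640 CPM against 2.75 and 4.62 CPM).

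The genes called between rescue and mutant lay almost all on chromosome 2. Of 44 located genes besides tra, 41 were on chromosome 2 (93.2%, exact 95% interval 81.3% to 98.6%), 17 on arm 2L and 24 on arm 2R, against 38.6% of the tested genes (Fisher's exact p = 3.29e-14). The located changed-back genes besides tra were all 12 on chromosome 2 (interval 73.5% to 100%, Fisher's exact p = 1.09e-05). In mutant against control the share on chromosome 2 was 41.0%, and in rescue against control 41.6%. The X chromosome held 11.3% of the genes called in mutant against control and 16.1% of the tested genes (Fisher's exact p = 0.00032).

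**Figure D4:**
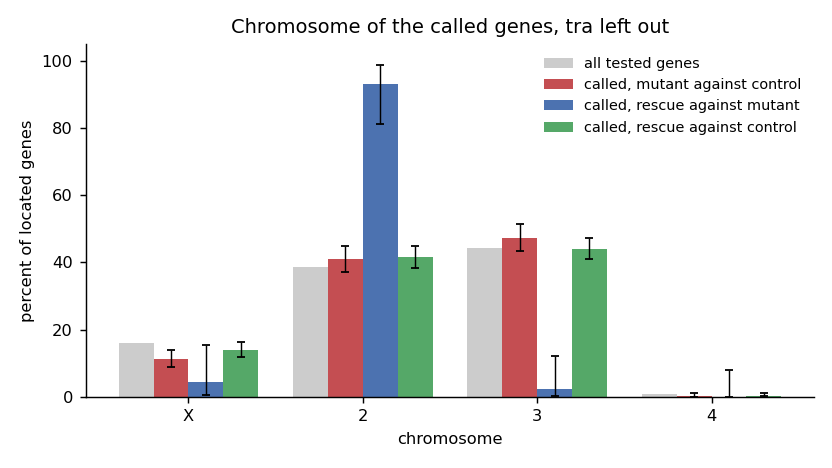
Percent of located genes (vertical axis) on chromosomes X, 2, 3 and 4 (horizontal axis) for all tested genes and for the genes called in each comparison, tra left out, with exact 95% binomial intervals as whiskers. Chromosome 2 held 93.2% of the genes called in rescue against mutant and 38.6% of the tested genes.

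The digestive, lysozyme and yolk protein genes that differed between mutant and control did not pass between rescue and mutant. Amy-d measured 7412 ± 630 and 7239 ± 955 CPM, LysD 3406 ± 367 and 3314 ± 765 CPM, and Yp1 0.179 ± 0.163 and 0.129 ± 0.189 CPM. In 20 of the 24 lists no member passed with edgeR. Of the 402 genes in them, 13 were higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 1 lower. Among 51 detoxification genes 1 rose and 2 fell (2 and 8 adjusted over the list alone; 0 and 2 without rescue replicate 2, 1 and 5 with the replicate block, 2 and 8 with DESeq2), with camera adjusted p = 0.0215 and adjusted p = 0.422 with an estimated correlation. Of 32 antimicrobial effectors 1 rose, DptA (12 adjusted over the list alone), and the set was higher with camera adjusted p = 2.32e-08 and adjusted p = 0.422 with an estimated correlation. Sets of enteroendocrine (camera adjusted p = 0.00151) and fat body markers (camera adjusted p = 0.00144) were higher, each with adjusted p = 0.422 with an estimated correlation, and 0 and 1 members rose adjusted over the list alone. Among the fat body markers Lsp2 had 28, 165 and 36 counts in rescue replicates 1, 2 and 3, Lsp1beta 43, 143 and 18, and Obp99b 45, 96 and 33. Neuronal markers were higher with camera adjusted p = 0.000954 and adjusted p = 0.282 with an estimated correlation. Ribosomal protein genes were lower with camera adjusted p = 7.58e-11 and adjusted p = 0.799 with an estimated correlation, at a median of -0.22. The transgene-associated list passed through tra (camera adjusted p = 0.000966 and adjusted p = 0.217 with an estimated correlation), and for sex determination camera adjusted p = 0.0773. For the other 16 lists camera adjusted p lay between 0.176 and 0.93. Among these the list median and mean differed in sign for dosage compensation (-0.02 and 0.26) and carbohydrate digestion (-0.07 and 0.16), and for Malpighian tubule and hindgut markers the median (0.01) differed from the direction of the test.

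Every left-out library moved the counts of 19 and 28 genes. Without mutant replicates 1, 2 or 3, 7, 7 and 8 genes rose and 14, 16 and 13 fell, and without rescue replicates 1, 2 or 3, 8, 8 and 10 rose and 14, 15 and 11 fell.

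The comparison of rescue with control asked which differences were present when tra had been returned to the stem cells. Amy-d, Mal-A2, LysC and LysD differed from control by amounts close to those in the mutant, and more enteroendocrine and neuronal markers passed. In total 483 genes rose and 469 fell. Amy-d rose by 2.35 ± 0.23 (edgeR adjusted p = 0.000573), LysC by 4.75 ± 0.39 (35.1 ± 13.1 to 946 ± 374 CPM, edgeR adjusted p = 0.000173), Lip3 by 3.92 ± 0.44 (edgeR adjusted p = 0.000973) and CG31089 by 4.66 ± 0.35 (edgeR adjusted p = 0.000103). Lower were Yp1 (-7.69 ± 1.14, edgeR adjusted p = 0.00401), Yp2 (-6.17 ± 0.80, edgeR adjusted p = 0.00213), SMC2 (-5.47 ± 0.35, edgeR adjusted p = 5.26e-05) and Jon99Fi (-2.45 ± 0.29, edgeR adjusted p = 0.00128). Yp3 measured -2.87 (edgeR adjusted p = 0.121), with 0.438, 0.204 and 4.17 CPM in the rescue libraries, and without rescue replicate 3 it was lower and passed (-5.15, edgeR adjusted p = 0.0262; 0.0262 to 0.291 over the alternatives). The stress-response gene TotM fell by 5.58 ± 1.24 (edgeR adjusted p = 0.0246; up to 0.0939 without rescue replicate 1, 2 or 3), and DptA rose by 5.37 ± 0.77 (edgeR adjusted p = 0.00356).

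Of the genes that rose in the mutant, 285 of 369 (77.2%) also rose in the rescue against control, and of those that fell, 218 of 304 (71.7%) also fell. Independent lists would share 17.7 and 14.1 genes. Simulated unchanged groups against the same control libraries shared at most 0, but unchanged groups give few calls, so this was likely beforehand. Neither number shows how much overlap the shared controls give where many genes are called. The fold changes correlated at 0.70 across genes, against 0.50 in simulation, with a covariance of 0.463 against 0.065, and part of the excess may come from the shared controls. The median log2 fold change of the genes that rose in the mutant was 1.17 there and 1.10 in the rescue, and of those that fell -1.21 and -1.05.

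Carbohydrate genes rose in 9 of 21 cases (14 adjusted over the list alone; 4 without rescue replicate 2), with camera adjusted p = 1.83e-08 and adjusted p = 0.437 with an estimated correlation. Of 24 enteroendocrine markers 7 rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 0.000168 and adjusted p = 0.464 with an estimated correlation. Tk rose from 99.0 ± 15.3 to 195 ± 14.3 CPM (0.98 ± 0.14, edgeR adjusted p = 0.00295) and Cadps from 3.80 ± 0.488 to 7.75 ± 1.20 CPM (1.03 ± 0.16, edgeR adjusted p = 0.00572). AstA, which encodes allatostatin A, rose from 39.5 ± 8.03 to 69.3 ± 9.10 CPM (0.81 ± 0.17, edgeR adjusted p = 0.0183; up to 0.0724 without rescue replicate 2 or 3). Of 11 neuronal markers 5 rose (6 adjusted over the list alone), among them brp from 3.31 ± 0.377 to 6.49 ± 0.476 CPM (0.97 ± 0.14, edgeR adjusted p = 0.00396), with camera adjusted p = 0.00039 and adjusted p = 0.437 with an estimated correlation. The neuronal marker ple measured 0.429, 0.635 and 5.08 CPM in the rescue libraries against 0.203 ± 0.0231 in control (3.33 ± 0.85, edgeR adjusted p = 0.0394; up to 0.095 without rescue replicate 3 or any 1 control library). Antimicrobial effectors rose in 6 of 32 cases (7 rose and 1 fell adjusted over the list alone; 4 rose without rescue replicate 2), with camera adjusted p = 0.00299 and adjusted p = 0.789 with an estimated correlation.

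Cell cycle genes fell in 6 of 49 cases (15 adjusted over the list alone), with camera adjusted p = 0.000332 and adjusted p = 0.789 with an estimated correlation. Without control replicate 3 the number was 4, without rescue replicate 2 it was 1, with the replicate block 3 and with DESeq2 18. Control replicate 3 held the highest levels of Mcm7, a replicative helicase subunit (9.42 against 2.30 and 1.91 CPM), and of CycB, cyclin B (7.35 against 1.07 and 1.54 CPM). Ribosomal protein genes fell in 9 of 79 cases (73 adjusted over the list alone), at a median of -0.58, with camera adjusted p = 2.01e-19 and adjusted p = 0.789 with an estimated correlation. Without control replicate 3, 67 ribosomal protein genes fell, and without rescue replicate 2 none did with edgeR. Under the 4 scalings the ribosomal count was 9, 9, 17 and 24, and with DESeq2 57. Detoxification genes rose in 8 and fell in 3 of 51 cases (12 and 5 adjusted over the list alone; 5 and 3 without rescue replicate 2; camera adjusted p = 0.0546). Lipid genes rose in 2 and fell in 5 of 27 cases (3 and 8 adjusted over the list alone; 2 and 2 without rescue replicate 2; camera adjusted p = 0.419), with Lip4 down from 34.1 ± 15.8 to 3.82 ± 1.47 CPM (-3.16 ± 0.38, edgeR adjusted p = 0.00143). Proteases fell in 3 of 30 cases (3 adjusted over the list alone; 1 without rescue replicate 2; camera adjusted p = 0.196). Fat body markers rose in 2 and fell in 3 of 13 cases (4 and 5 adjusted over the list alone; 5 fell without control replicate 3; camera adjusted p = 0.794). The visceral muscle set was lower with camera adjusted p = 0.0169 and adjusted p = 0.789 with an estimated correlation. In 7 lists of 69 genes, muscle among them, no member passed with edgeR (5 higher and 13 lower at an unadjusted p under 0.05, 2 and 6 with DESeq2). Sets that passed only with the replicate block were JAK-STAT, EGFR and JNK signalling (camera adjusted p = 0.0389 against 0.0546) and detoxification (0.0261 against 0.0546), with adjusted p = 0.826 and 0.789 with an estimated correlation. For the other lists camera adjusted p lay between 0.189 and 0.81. For heat shock genes the list median (0.05) and mean (-0.08) differed in sign.

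Without rescue replicate 1, 2 or 3, 309, 277 and 221 genes rose and 151, 151 and 139 fell. Fits on the 6 libraries alone called 294 and 200 genes.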

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

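The shares of alignments outside the gene counts were set for comparison before the data were examined, and the reading by numbered pairs and the tests of accessory gland and testis transcripts below were chosen only after results had been seen.

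Some alignments that the gene counts do not use took larger shares than in control. Alignments at more than 1 place made up 18.76 ± 0.62% of counted alignments in the rescue and 15.31 ± 1.03% in control (n = 3 each, exact p = 0.1), with 19.43 ± 3.55% in the mutant (exact p = 0.2 against control, with a larger share in the mutant in all 3 numbered pairs). Alignments outside annotated genes made up 1.707 ± 0.122% in the rescue and 1.398 ± 0.0929% in control (exact p = 0.1), while the mutant was at 1.408 ± 0.0967% (exact p = 0.7 against control). Alignments matching more than 1 gene made up 1.008 ± 0.0368% in the mutant and 1.072 ± 0.0238% in the rescue, against 0.865 ± 0.0396% in control (exact p = 0.1 for each). With 3 against 3 libraries 0.1 is the smallest p an exact test can give. The sequences behind these alignments were not examined and no explanation was tested.

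The X-linked RNAs roX1 and roX2, which coat the single X chromosome of males, were high in 1 library. roX1 had 853 counts in rescue replicate 2 and 43 to 90 in the other 8 libraries, and roX2 had 14 counts there and 0 or 1 elsewhere. The same library held the most counts of the fat body markers Lsp2 (165, with 2 to 36 elsewhere), Lsp1beta (143, with 0 to 43) and Obp99b (96, with 0 to 45). Neither group difference of roX1 that includes the rescue passed (edgeR adjusted p = 0.0907 against control, with 0.0578 to 0.632 over the alternatives). A male reproductive tract among these midguts stays open, and the markers below cannot show that a male was in the pool. The rescue flies carried the tra mutation, and tra directs female somatic differentiation. Accessory gland and testis markers therefore need not come from a separate male. This does not extend to roX1 and roX2, which had 55, 87 and 65 and 0, 1 and 0 counts in the mutant libraries. The tra mutation alone did not raise them there. In rescue replicate 2 accessory gland markers other than Est-6 summed to 0.849 CPM of library totals. This sum lay within the 0.247 to 1.30 of the other libraries, but 3 members seen in nearly every library held 58 of the 72 counts. Among the rest Acp76A (4 counts), Acp26Aa (3) and Dup99B (2) were highest in this library, with 0, 1 and 0 at most elsewhere, while Acp26Ab, Acp29AB, Acp36DE, Acp95EF, Acp98AB and SP were at 0 in it and Acp62F had 5 counts both there and in control replicate 3. Testis markers other than mia summed to 0.141 CPM of library totals there, below the 0.240 of rescue replicate 1. Other male tissue stays open as well, because the 6 Y-linked genes analysed here were at 0 in all libraries. A sum of 0 would also be found for tissue that does not transcribe them, or if these genes were not counted. The 37 mitochondrially encoded genes were at 0 in all libraries too, so the zeros need not be a measurement. The design gives no group that would set a single replicate apart.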

How the results depend on the processing

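The combination of the replicate block with the 6 libraries compared, and the counts of list members without control replicate 3 or rescue replicate 2, were chosen only after results had been seen.

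With DESeq2 in place of edgeR, 702 genes were higher and 656 lower in mutant against control (369 and 304 with edgeR), 60 and 62 in rescue against mutant (19 and 28), 825 and 896 in rescue against control (483 and 469), and 41 changed and changed back (15). Fits on the 6 libraries compared gave 239 higher and 177 lower in mutant against control, 44 lower in rescue against mutant, and 294 higher and 200 lower in rescue against control. A filter of 1 CPM in 3 libraries gave 18 lower in rescue against mutant. RLE factors, upper-quartile scaling, library totals and no filter kept every count of a comparison within 1.5 times. The cause of the moves was not tested.

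The correlations of same-number libraries varied more for rescue pairs (0.024, 0.25 and 0.03 with control, and 0.096, 0.073 and -0.237 with mutant). That of control and rescue replicate 2, at 0.25, was the highest of all, while the others were below those of control and mutant pairs. The rescue numbers were not treated as pairs. With the replicate block, 406 genes were higher and 353 lower in mutant against control, 15 and 23 in rescue against mutant, 478 and 439 in rescue against control, and 14 changed back, 10 of them among the 15. With the block and only the 6 libraries, 227 were higher and 152 lower in mutant against control.

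Leaving out 1 library at a time gave 200 to 406 higher and 114 to 352 lower in mutant against control, 7 to 10 higher and 11 to 16 lower in rescue against mutant, 221 to 466 higher and 139 to 508 lower in rescue against control, and 8 to 24 that changed back. A smaller group has less power to call genes, but that alone does not account for the falls. Fits without control replicate 1, 2 or 3 have the same size and gave 406, 341 and 346 higher in mutant against control. Without mutant replicate 1, 2 or 3 the numbers were 201, 200 and 236. In both comparisons with control the lowest count came without a mutant or a rescue library. Rescue against mutant has no control library to leave out. The cause was not tested.

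Of 23 list tests that passed with camera, 0 passed with an estimated correlation, and the number of tests that passed was 12 with fry, 26 with the block and 23 with RLE factors. With fry the sex determination list turned from higher to lower in mutant against control (adjusted p = 0.0291). Of 192 counts of list members, 29 moved without control replicate 3 or rescue replicate 2. Of the 147 calls of named genes, 93 held in every alternative, 54 were lost in at least 1 fit that left out a library, and 0 changed direction. Of 5770 values of named genes, 253 lost a call and 90 gained one.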

Other observations

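The group of neighbours around elfless, the neighbours of tra, the count of neighbouring calls, the level of SMC2 and the shares of genes on chromosome 2 were chosen for testing only after results had been seen.

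Genes that rose in the mutant lay beside one another. On arm 2L, 5 neighbours all rose: elfless (ratio of summed counts 751, interval 208 to 6205), rdo (5.96 ± 0.66), Arr1 (6.33 ± 0.62), ninaD (2.55 ± 0.58, edgeR adjusted p = 0.031) and CG31741 (4.62 ± 0.57), while the flanking CG5674 measured 0.10 (edgeR adjusted p = 0.719). Of these, elfless and rdo returned in the rescue. Arr1 and CG31741 were above control there (3.73 ± 0.58 and 3.25 ± 0.54), and ninaD did not pass (1.88 ± 0.57, edgeR adjusted p = 0.067). Arr1 was at 14.0 CPM in the mutant and 2.31 CPM in the rescue, a difference that did not pass (-2.60, edgeR adjusted p = 0.0754) and did with DESeq2, without a filter and with the 6 libraries alone. Over all genes called in mutant against control, 93 neighbouring pairs changed in the same direction, against a mean of 22.13 and a highest value of 42 in 10000 permutations (permutation p = 0.0001, the smallest these can give). The counts were 102 against 43.43 in rescue against control (permutation p = 0.0001) and 2 against 0.21 in rescue against mutant (permutation p = 0.02). Tandem paralogs such as the lysozyme and maltase genes are among these neighbours, so the count does not separate shared regulation from shared reads. Nor does it separate them from differences of chromosome regions between the stocks.

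SMC2 was expressed at 206 CPM in control, while the other 48 cell cycle genes had a median of 3.51 CPM and a highest level of 142.5 CPM (E2f1). Their median log2 fold change in the mutant was -0.90 and the lowest -1.70, against -5.36 for SMC2. Among the 5 tested neighbours of tra on each side, Apl rose in the mutant (2.62 ± 0.42, edgeR adjusted p = 0.00636, at most 0.0288 over the alternatives) and remained higher than control in the rescue (2.42 ± 0.42, edgeR adjusted p = 0.00814). The neighbour spd-2 measured -1.37 in the mutant without passing (edgeR adjusted p = 0.0967) and was lower than control in the rescue (-2.12 ± 0.46, edgeR adjusted p = 0.0228), a call lost with the 6 libraries alone and without control replicate 3 or rescue replicate 1, 2 or 3 (edgeR adjusted p up to 0.0862). A difference of that chromosome region between stocks was not separated from the loss of tra.

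Genes called between rescue and mutant concentrated on chromosome 2. The share was 93.2% of 44 located genes besides tra, and 100% of the 12 that changed and changed back, against 38.6% of tested genes. In 14 alternatives it lay between 82.2% and 100%. Among genes without a call, an unadjusted p under 0.05 was also more frequent on chromosome 2 (7.43% against 2.96%, odds ratio 2.63, interval 2.16 to 3.21), while in mutant against control that odds ratio was 1.10 (interval 0.98 to 1.23). A strain difference of the second chromosome between the 2 stocks may therefore account for many of these calls, and an effect of tra in stem cells on these genes stays open and was not tested apart from it.

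For mutant against control, no chromosome held a share of called genes near 1.5 times its share of tested genes. The highest relative to its share was 47.4% on chromosome 3 against 44.4%. This argues against a strain difference of 1 chromosome as the whole source, but not against differences on several chromosomes. The 12 located genes besides tra that changed and changed back all lay on chromosome 2. For these, CG34215, elfless and rdo among them, a difference of the second chromosome of the mutant stock was not separated from the loss of tra. The yolk protein genes fell. The 6 tested ovary markers had a median of 0.15 (-0.38 to 0.74), but they were read at similar levels in the mutant, so a small share of ovary could be hidden. Among the 15 ovary markers not tested, the highest control count was 35 (bam, control replicate 3), and 10 had under 10 counts in every library. Yp1 had 4309, 2369 and 586 counts in control. These low counts argue against ovary tissue on the control midguts as the source. Fat body on the control midguts could not be told apart from an effect of tra on the yolk protein genes. The 9 other fat body markers had a median of -0.16 over values of -3.21 to 2.57, and 4 of them were not lower.

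Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls: 673 with a highest other of 0, 47 with a highest other of 1, and 952 with a highest other of 7. In mutant against control 4 of the splits part all 3 numbered pairs, and the highest of the others among them called 0. For the genes that changed and changed back, 1 of 100 splits of the 9 libraries gave as many as 15, and the highest other gave 7. Of these, 36 splits part all 3 numbered pairs of control and mutant libraries, as the real one does, and among them again 1, the real one, gave as many (highest other 7). The split that gave 7 kept the 3 mutant libraries together. The other splits mix groups that differ, which widens the spread and lowers their calls, so low counts there were likely beforehand. At most, the splits show that the real groups differ. They do not tell a difference between stocks or cultures from an effect of tra.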
